A study of Danio rerio with 6 samples.

How the data were processed

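RNA was sequenced from GFP-positive cells that had been sorted from trunks of 14 hours post fertilisation zebrafish embryos after removal of brain and tail, per the labels' protocols, with 2 libraries for each of 3 reporter lines (nkx2.2a, olig2 and dbx1b). The submitters' processing notes name FastQC 0.11.3, Bowtie 1.1.1 and the genome build GRCz10, without saying what each was used for. The deposited counts are mapped reads per RefSeq transcript for 54437 transcripts, in the layout of an alignment index summary, and were not normalised. Every count is even, so the 2 mates of a fragment were both counted. Reads without a mapped transcript (66.6% to 80.6% per library) stayed out of library sizes and tests. The deposited FPKM values are the authors' reads per 1000 bases of transcript per 1000000 mapped reads: recomputed from the counts, 326622 of 326622 values agreed within a relative 1e-06. The authors also deposited a table of group mean FPKM values plus 0.001 and their log2 ratios. In 1151 of its 54437 rows the means belong to the transcript named in the row, and 0 of these rows have an FPKM above 0, although the sorted values of its 3 mean columns equal those computed from the FPKM table. It was not used for any result.

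Counts were summed over the transcripts of each symbol, giving 30677 symbols, of which 21329 were found among the current symbols or synonyms of the zebrafish RefSeq table (assembly GRCz12tu). That assembly is not the authors' build, so no coordinates are given. How reads that match several transcripts were assigned is not given in the sources used here, so genes with near-identical copies are uncertain as single genes, and strand was not considered.

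The main test was edgeR 4.0.16 (R 4.3.3) with its default quasi-likelihood fit, filterByExpr (minimum count 10), TMM scaling and 1 mean per group over all 6 libraries, which left 3 residual degrees of freedom. Of the symbols, 19129 were tested. The common dispersion was 0.779, a biological coefficient of variation of 0.883, and the prior degrees of freedom were 6.27. Genes were called at Benjamini-Hochberg adjusted p under 0.05, log2 fold changes have standard errors derived from the F statistic, and CPM values are TMM-scaled with mean ± SD (n = 2). The reporter genes, and separately cdh2, cdh11 and pcdh19, picked from general knowledge, were adjusted over their 9 tests. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with prior count 2) and adjusted over 27 lists; of 28 lists defined, the one of mitochondrially encoded genes had 0 members among the symbols. A count adjusted over the list alone corrects the edgeR p of a list's members for that list only. Some lists share members: notochord and ventral midline share 5 genes. The p-values measure the spread between these samples, since the labels do not say that libraries come from separate embryo pools; floors of 3 fragments cover counting error only. Line, form of GFP (membrane GFP in the nkx2.2a line only, per the labels), sort and group coincide, so a difference between groups can also be one between transgenic lines, reporters or sorts.

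Groups, designs, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The rule named, for each comparison, the 3 reporter genes and cdh2, cdh11 and pcdh19, up to 4 members of each list past adjusted p 0.05 over all genes, and the 8 genes with the largest positive and the 8 with the largest negative fold changes among those past it with separated libraries, 5 CPM or more and a name other than a clone name, up to 30 in all. No gene beyond the 6 always named met it, so the list examples were chosen after their values were seen, from members past the adjustment over the list alone, and cut to the limit of 30 after their stability had been seen.

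Counts were simulated with the dispersions estimated here and 100 genes changed at each size, drawn only from genes of higher mean expression. In nkx2.2a over olig2, nkx2.2a over dbx1b and olig2 over dbx1b, the edgeR step on 19129 genes called 23%, 9% and 19% of genes changed by a log2 of 2. It called 78%, 73% and 78% of those changed by 4, and 11, 5 and 15 of 18929 unchanged genes. These shares do not carry over to all genes of the data. For example, phlda3 in olig2 over dbx1b cells (log2 fold change -6.93) was not called over all genes (edgeR adjusted p = 0.170). Libraries of a group differed by far more than sampling noise (chi-square per degree of freedom 45.4, 41.8 and 39.6 for nkx2.2a, olig2 and dbx1b), so none was counted as a duplicate.

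Alternatives were RLE scaling, no composition scaling, DESeq2 1.42.0 on the same genes, no filter beyond 1 count, a filter of 1 CPM, the replicate number as a block, only the 4 libraries compared, a log2 fold threshold of 1, transcripts as features, camera with an estimated correlation, fry, and leaving out each library in turn. DESeq2 was first run on unfiltered genes, and was moved to the filtered genes after that result was seen. It left 2226, 3338 and 2596 of these genes without an adjusted p, in nkx2.2a over olig2, nkx2.2a over dbx1b and olig2 over dbx1b, so the genes adjusted over differ as well as the tool. Chosen after seeing the data were fragments in place of reads, edgeR's bias-adjusted quasi-likelihood dispersion, a filter of 10 CPM, both together, limma-trend on log2(FPKM + 1) with FPKM summed per gene, leaving out LOC101882117, and limma voom with quality weights. The result for 1 further pattern is not reported here. Tests of explanations used 1000 bootstrap draws over genes, 10000 random lists matched on mean expression, and libraries thinned to 3.25 M fragments. Tables and plots were made with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.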

Results

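Gene expression was measured by RNA sequencing in GFP-positive cells sorted from the trunks of wild-type zebrafish embryos at 14 hours post fertilisation. The cells came from 3 transgenic lines in which nkx2.2a, olig2 or dbx1b regulatory sequence drives GFP, in the nkx2.2a line a membrane form of it. These genes mark the p3 domain next to the floor plate, the motor neuron progenitor domain (pMN) and the more dorsal p0 domain of the ventral neural tube. Each group had 2 libraries, numbered 1 and 2. The nkx2.2a libraries held 5.83 and 3.59 M (1000000) fragments mapped to transcripts, the olig2 libraries 3.25 and 4.17 M, and the dbx1b libraries 5.90 and 6.93 M. The mapped share of all fragments was 28.1% and 19.6%, 19.4% and 22.1%, and 33.4% and 29.7% in the same order. A single fragment was worth 0.144 to 0.307 CPM (counts scaled to 1000000 mapped reads), and a count of 0 allowed a level of up to 0.433 to 0.922 CPM per library. An uncharacterised transcript, LOC101882117, took 3.47% and 7.72% of the mapped reads in the nkx2.2a libraries, 4.47% and 2.62% in the olig2 libraries, and 0.903% and 2.03% in the dbx1b libraries.

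Only the dbx1b libraries resembled each other more than they resembled any other library, with a Spearman correlation of log2 CPM of 0.884. The nkx2.2a libraries correlated at 0.776, while nkx2.2a library 1 reached 0.827 and 0.851 with the dbx1b libraries and 0.783 with olig2 library 1. The highest values, 0.884, 0.851 and 0.827, were those between the libraries with the most mapped fragments (5.83, 5.90 and 6.93 M). Likeness between libraries was therefore not separated from their depth. The olig2 libraries correlated at 0.754, below olig2 library 1 with nkx2.2a library 1 (0.783) or dbx1b library 2 (0.775). Over the 12 pairs between groups the correlation was 0.704 to 0.851. The first 3 principal components held 28.5%, 27.8% and 21.5% of the variance. The dbx1b libraries lay next to each other on components 1 and 3, with nkx2.2a library 2 between them on component 2. On component 1, nkx2.2a library 2 lay apart from nkx2.2a library 1, and the olig2 libraries lay apart on component 3.

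The gene behind each reporter was most abundant in its own sort. Transcripts of nkx2.2a, a transcription factor gene of the p3 domain, averaged 429 ± 92.6 CPM (SD, n = 2) in the nkx2.2a cells, 17.4 ± 12.96 CPM in the olig2 cells and 0.904 ± 0.515 CPM in the dbx1b cells. Those of olig2, which specifies motor neuron progenitors, averaged 172 ± 66.9 CPM in the olig2 cells, 44.9 ± 36.2 CPM in the nkx2.2a cells and 2.94 ± 1.62 CPM in the dbx1b cells. Transcripts of dbx1b, a homeobox gene of p0 progenitors, averaged 199 ± 23.2 CPM in the dbx1b cells, 30.4 ± 26.7 CPM in the nkx2.2a cells and 13.1 ± 5.51 CPM in the olig2 cells. In edgeR's quasi-likelihood test, with p adjusted over the 9 reporter tests, 8 of the 9 differences passed. The log2 fold change of nkx2.2a was 4.62 ± 0.67 (SE) in nkx2.2a over olig2 cells (adjusted p = 2.1e-04) and 8.85 ± 0.83 in nkx2.2a over dbx1b cells (adjusted p = 1.5e-05). That of olig2 was -1.94 ± 0.72 in nkx2.2a over olig2 cells (adjusted p = 0.0271) and 5.86 ± 0.87 in olig2 over dbx1b cells (adjusted p = 2.1e-04). That of dbx1b was -2.72 ± 0.72 in nkx2.2a over dbx1b cells (adjusted p = 0.00542) and -3.92 ± 0.76 in olig2 over dbx1b cells (adjusted p = 0.001002). The ventral sorts shared part of each other's reporter transcripts, and both also held dbx1b transcripts, so sharing was not limited to the ventral pair. The gene nkx2.2a was higher in olig2 than in dbx1b cells by 4.23 ± 0.70 (adjusted p = 3.7e-04). The gene olig2 was higher in nkx2.2a than in dbx1b cells by 3.91 ± 0.79 (adjusted p = 0.00112). The difference that did not pass was that of dbx1b in nkx2.2a over olig2 cells, 1.21 ± 0.69 (adjusted p = 0.115), which was -0.17 without nkx2.2a library 2 and 1.91 without nkx2.2a library 1 (adjusted p = 0.0123). The dbx1b difference between nkx2.2a and dbx1b cells was -2.01 without nkx2.2a library 1 and -4.12 without nkx2.2a library 2. The olig2 difference between nkx2.2a and olig2 cells was -3.15 without nkx2.2a library 2 and missed the threshold without nkx2.2a library 1 (-1.29, adjusted p = 0.112) or olig2 library 1 (-1.49, adjusted p = 0.106).

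**Figure D1:**
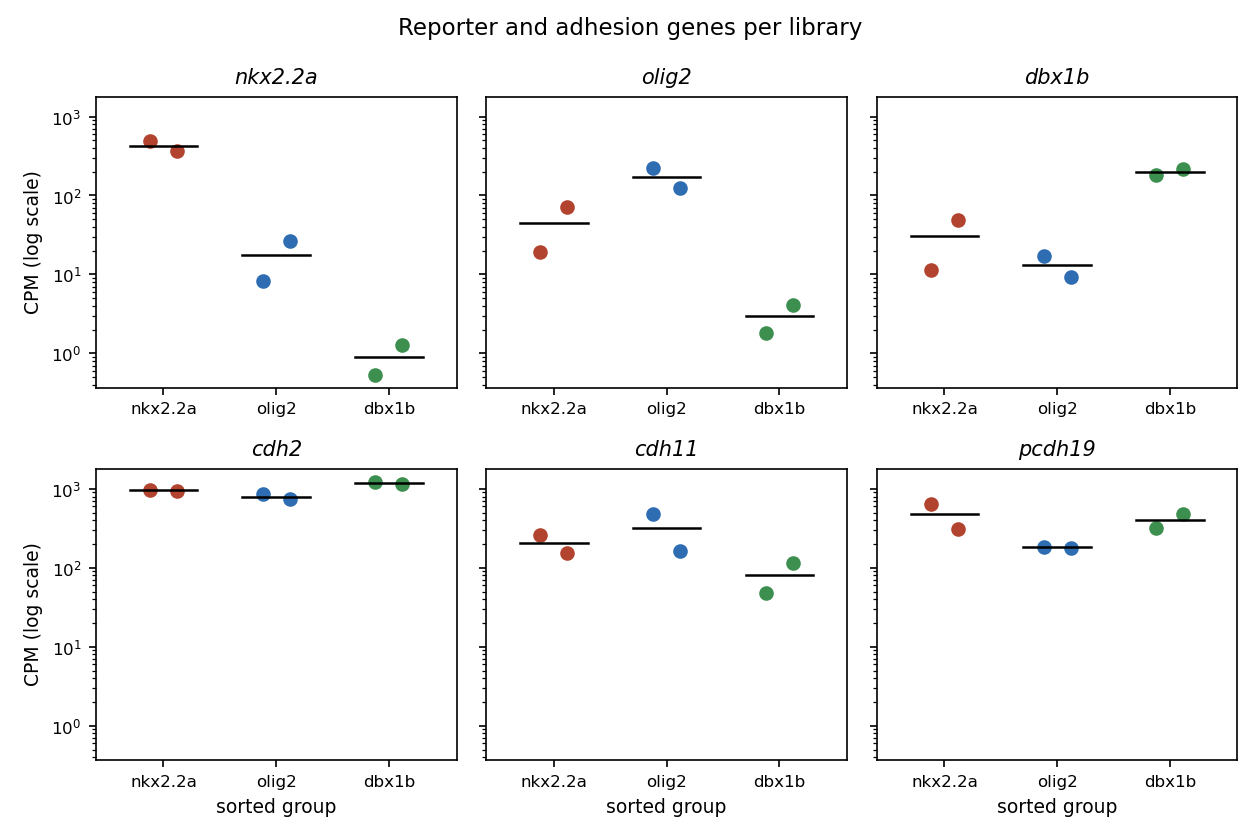
CPM (log scale) of the 3 reporter genes and 3 adhesion genes in each library, by sorted group. Points are libraries, library 1 on the left, and bars are means of 2 libraries. The reporter means in their own sorts are 429, 172 and 199 CPM, and cdh2 lies between 798 and 1192 CPM in the 3 groups.

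Adhesion molecules let cells bind neighbours of their own kind, and 3 of their genes were picked before the data were examined. The classical cadherin gene cdh2 (N-cadherin) was abundant everywhere, at 960 ± 28.5 CPM in nkx2.2a cells, 798 ± 75.3 CPM in olig2 cells and 1192 ± 37.4 CPM in dbx1b cells. Transcripts of cdh11, a type II cadherin gene, averaged 205 ± 73.9, 324 ± 227 and 80.8 ± 47.0 CPM in the same order, and those of the protocadherin gene pcdh19 averaged 482 ± 241, 182 ± 5.04 and 399 ± 109 CPM. With p adjusted over the 9 tests of these genes by edgeR, 2 differences passed. The gene cdh11 was higher in olig2 than in dbx1b cells by 2.00 ± 0.62 on the log2 scale (adjusted p = 0.0451). The gene pcdh19 was higher in nkx2.2a than in olig2 cells by 1.40 ± 0.42 (adjusted p = 0.0451, 95% interval 0.45 to 2.36). The log2 difference of pcdh19 in olig2 over dbx1b cells was -1.13 ± 0.42 (adjusted p = 0.0727). None of the 3 cdh2 differences passed, and their intervals allowed changes of -1.19 to 0.88. None of these genes passed over all genes tested (adjusted p = 0.450 for cdh11 and 0.535 for pcdh19). Of the 75 tested cadherin and protocadherin genes, 0 passed edgeR's test in any comparison with p adjusted over the list alone, and camera gave adjusted p = 0.893, 0.688 and 0.686. The cdh11 call was lost without olig2 library 1, where the difference was 1.00 (adjusted p = 0.212), or dbx1b library 1 (1.48, 0.131). It was lost too without nkx2.2a library 1 (2.00, 0.0593) and with the replicate number as a block (1.83, 0.0787). The pcdh19 call was lost without nkx2.2a library 1, where the difference was 0.77 (adjusted p = 0.242), and at a similar size without olig2 library 1 (1.43, 0.109), without olig2 library 2 (1.39, 0.0794) and with the block (1.37, 0.0787). Calls were also gained: pcdh19 in olig2 over dbx1b cells without nkx2.2a library 2 (-1.15, adjusted p = 0.0278) or a filter (-1.11, 0.0154), and cdh11 in nkx2.2a over dbx1b cells without dbx1b library 2 (2.13, 0.0305) or a filter (1.36, 0.0102).

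The comparison of nkx2.2a with olig2 cells asks how the p3 and pMN sorts differ. At camera's preset correlation, the nkx2.2a cells carried more transcripts of ventral midline, axon guidance and notochord genes and fewer Hox transcripts, and brain and epidermis lists passed with calls that single libraries undo. None of these 6 lists passed with an estimated correlation (camera adjusted p = 0.438 to 0.535) or with fry (fry adjusted p = 0.0958 to 0.173). At an estimated correlation all 21 list calls of the 3 comparisons were lost. This held also where the estimate lay below the preset 0.01, as for axon guidance here (-0.0253). A loss at this setting therefore cannot show that correlated members made a call. The other estimates here lay between 0.0158 and 0.291. Among ventral midline genes, sulf1, which encodes a heparan sulfate sulfatase, stood at 366 ± 76.3 against 81.7 ± 3.18 CPM (4.49-fold), the Hedgehog ligand gene shha at 149 ± 53.9 against 26.7 ± 7.89 CPM (5.601-fold), and shhb at 56.0 ± 12.5 against 1.34 ± 1.46 CPM. The cilia regulator gene foxj1b was at 54.3 ± 25.4 against 1.93 ± 0.716 CPM. Of 21 tested members of the ventral midline and p3 list, 5 were higher and 0 lower in edgeR's test with p adjusted over the list alone. These 5 include nkx2.2a, whose reporter defined the sort. The list median was 1.71 (camera adjusted p = 4.1e-04, and 0.535 with an estimated correlation).

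Axon guidance genes were higher as a list, with a median of 1.08 (camera adjusted p = 0.00258; adjusted p = 0.438 with an estimated correlation), and 7 of 35 rose and 0 fell adjusted over the list alone. They included the guidance ligand gene slit2, at 105 ± 47.0 against 5.25 ± 3.98 CPM, and the neuropilin gene nrp1a, at 58.8 ± 21.7 against 4.45 ± 0.593 CPM. The notochord list had a median of 1.27, or 1.101 with members at 0 in a group set to their bound (camera adjusted p = 0.00110; adjusted p = 0.438 with an estimated correlation), and 6 of 28 rose adjusted over the list alone. They included the collagen gene col2a1a (log2 fold change 2.11 ± 0.46) and the matricellular gene ctgfa (2.57 ± 0.51), and shha and shhb are members of this list too. Epidermis and periderm markers had a median of 0.80 (camera adjusted p = 0.00258; adjusted p = 0.438 with an estimated correlation), with 6 of 34 higher. Among them were the claudin gene cldnb (5.82 ± 1.01), the E-cadherin gene cdh1 (2.39 ± 0.51) and the simple-epithelium keratin gene krt8 (1.93 ± 0.38). The brain list had a median of 0.95 (camera adjusted p = 0.0189; adjusted p = 0.535 with an estimated correlation), with 4 of 28 higher. Among them were the forebrain genes six3b (3.92 ± 0.96) and fezf2 (3.43 ± 0.93) and the hindbrain gene egr2b (1.46 ± 0.39). Hox genes had a median of -1.34 (camera adjusted p = 2.1e-06; adjusted p = 0.535 with an estimated correlation), and 36 of the 44 tested were negative. Only hoxa9a passed over the list alone, at 10.5 ± 2.19 against 78.0 ± 15.8 CPM.

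Other lists did not pass camera as a whole but held single members that passed over the list alone. Both p0 to p2 progenitor genes that passed, pax6a (-2.26 ± 0.44) and sp8a (-2.54 ± 0.59), were lower in nkx2.2a cells (camera adjusted p = 0.768 for 22 members). The Ephrin list had 3 of 25 members higher (camera adjusted p = 0.210), including efna5a (3.34 ± 0.84) and ephb3a (3.36 ± 0.83). With a library left out, ephb3a ranged from 2.66 to 4.79. The adhesion gene bcam was higher at 524 ± 239 against 73.1 ± 0.151 CPM, the only one of 40 other adhesion molecules to pass (camera adjusted p = 0.596). The retinoic acid, FGF and Wnt list had 3 of 55 higher, including cyp26c1 (2.48 ± 0.46) and cyp26b1 (3.37 ± 0.79), which encode retinoic acid-degrading enzymes (camera adjusted p = 0.320). In nkx2.2a, olig2 and dbx1b cells cyp26c1 stood at 291 ± 115, 52.1 ± 7.65 and 333 ± 133 CPM, so its difference reflects a low olig2 level. The tailbud gene cdx4 was lower, at 89.0 ± 4.04 against 336 ± 50.5 CPM (1 of 24 in its list, camera adjusted p = 0.893), and the hatching enzyme gene he1a was higher, at 300.4 ± 82.6 against 13.1 ± 16.7 CPM (2 of 10 in its list, camera adjusted p = 0.0639). The log2 fold change of he1a, 4.51 ± 1.32, was 7.95 without olig2 library 2.

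No single gene passed over all 19129 genes tested: edgeR called 0 at adjusted p under 0.05, with 1673 genes at unadjusted p under 0.05 where chance gives 956. DESeq2 called 569 (422 higher, 147 lower). edgeR's count became 6 without olig2 library 2 or dbx1b library 1 and 5 without dbx1b library 2. The brain call was lost without nkx2.2a library 1 (adjusted p = 0.0768), nkx2.2a library 2 (0.0712) or olig2 library 2 (0.0562), and the epidermis call without nkx2.2a library 1 (0.0692) or olig2 library 2 (0.0605). Of the 25 list examples named for this comparison, chosen after their values and cut after their stability were seen, 9 kept their call under all 10 alternatives run for them and 16 lost it without nkx2.2a library 2. The least stable, egr2b and fezf2, kept it in 5 of 10.

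The comparison of nkx2.2a with dbx1b cells sets the most ventral sort against the p0 sort. At camera's preset correlation, the nkx2.2a cells carried more ventral midline, notochord, epidermis and brain transcripts, and fewer transcripts of p0 to p2 progenitors, Hox genes, presomitic mesoderm and tailbud genes and stress genes. None of the 12 lists that passed did so with an estimated correlation (camera adjusted p = 0.139 to 0.916). The estimates of the tailbud (-0.00777) and pMN (-0.0561) lists lay below the preset 0.01. Correlated members therefore do not account for the loss of those calls. The estimates of the other lists lay between 0.0158 and 0.662. With fry, the tailbud list alone passed (fry adjusted p = 0.0231). The pMN, hatching gland, p0 to p2, stress, cell cycle and ribosomal calls hang on single libraries. Of 21 ventral midline and p3 members, 7 were higher and 0 lower adjusted over the list alone by edgeR (median 1.75, camera adjusted p = 9.7e-09; adjusted p = 0.239 with an estimated correlation). Besides nkx2.2a itself, the homeobox gene nkx2.9 stood at 84.9 ± 53.3 against 1.57 ± 1.97 CPM (log2 fold change 5.72 ± 1.11, and 8.79 without dbx1b library 2) and the netrin gene ntn1b at 130 ± 6.51 against 17.5 ± 8.49 CPM (2.89 ± 0.56, from 2.45 without dbx1b library 1 to 3.51 without dbx1b library 2). The forkhead gene foxa was at 212 ± 16.0 against 34.5 ± 27.6 CPM (2.62 ± 0.63, from 1.96 without dbx1b library 1 to 3.84 without dbx1b library 2). The pMN list had a median of 1.39 (camera adjusted p = 0.0448; adjusted p = 0.239 with an estimated correlation), with 4 of 12 higher and 1 lower. The homeobox gene nkx6.1 was higher at 134 ± 7.07 against 23.5 ± 5.18 CPM, whereas the motor neuron gene mnx1 was lower at 5.26 ± 0.598 against 52.4 ± 26.7 CPM. Of 22 p0 to p2 genes, 3 were lower and 0 higher (median -1.20, camera adjusted p = 0.00134; adjusted p = 0.239 with an estimated correlation): pax6a (-2.34 ± 0.44), dbx1b and prdm12b (-3.85 ± 1.104). Of these, dbx1b kept its list call in 6 of 10 alternatives and prdm12b in 5, with an edgeR adjusted p of up to 0.637 (without dbx1b library 1).

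The tailbud list had the largest median in size, and Hox genes were lower too. Of 24 presomitic mesoderm and tailbud members, 14 were lower in nkx2.2a cells and 0 higher adjusted over the list alone (median -2.60, camera adjusted p = 4.1e-10; adjusted p = 0.139 with an estimated correlation). The presomitic transcription factor gene msgn1 was at 15.21 ± 4.399 against 212 ± 83.9 CPM, cdx4 at 89.0 ± 4.04 against 390.2 ± 78.6 CPM and the segmentation clock gene her7 at 7.16 ± 1.42 against 87.4 ± 21.9 CPM. Hox genes had a median of -1.66, with 10 of 44 lower and 0 higher (camera adjusted p = 8.9e-14; adjusted p = 0.239 with an estimated correlation), including hoxa9a (-3.49 ± 0.61) and hoxc8a (-2.25 ± 0.63, and -3.41 without nkx2.2a library 1). The brain list had a median of 1.27 (camera adjusted p = 8.97e-04; adjusted p = 0.239 with an estimated correlation), though six3b (4.22 ± 0.97) was the only one of 28 to pass. The notochord list had a median of 1.45, with 5 of 28 higher and 1 lower (camera adjusted p = 3.7e-04; adjusted p = 0.239 with an estimated correlation). The cartilage and notochord collagen gene col9a2 rose by 3.58 ± 0.58, while ta, a brachyury gene of both notochord and tailbud, fell by 3.92 ± 0.97. With a library left out, the log2 fold change of ta ranged from -5.37 to -3.23. Epidermis and periderm markers had a median of 1.34, with 6 of 34 higher (camera adjusted p = 6.0e-06; adjusted p = 0.239 with an estimated correlation), including the epithelial adhesion gene epcam, at 187 ± 0.376 against 20.8 ± 7.05 CPM, and krt8 (2.29 ± 0.38). Hatching gland and germ cell markers had 4 of 10 higher (median 2.52, camera adjusted p = 0.0335; adjusted p = 0.565 with an estimated correlation), all of them hatching gland genes, including he1a, at 300.4 ± 82.6 against 1.57 ± 1.97 CPM, and the cathepsin gene ctslb (6.40 ± 1.77, and 10.38 without dbx1b library 2).

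Stress and dissociation genes had a median of -0.48, with 3 of 45 lower and 0 higher (camera adjusted p = 0.00497; adjusted p = 0.239 with an estimated correlation). The 3 were the small heat shock gene hspb1, at 711 ± 138 against 2607 ± 318 CPM, the cyclin G gene ccng1 (-1.62 ± 0.31) and the pro-apoptotic gene bbc3 (-5.24 ± 1.34). The bbc3 call was kept in only 4 of 10 alternatives, with an edgeR adjusted p of up to 0.315 (without dbx1b library 1). Cell cycle genes had a median of -0.50 over 37 members (camera adjusted p = 0.00285; adjusted p = 0.239 with an estimated correlation) and ribosomal protein genes one of -0.26 over 89 (camera adjusted p = 0.0484; adjusted p = 0.916 with an estimated correlation), with 0 members of either past edgeR's test over the list alone. In the neural progenitor and Notch list, the Notch ligand gene dlc was lower (-2.85 ± 0.56) and the progenitor gene sox1b higher (4.23 ± 0.84), 1 of 34 each way (camera adjusted p = 0.580).

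Over all 19129 genes, edgeR called nkx2.2a alone (adjusted p = 0.0312), with 1200 genes at unadjusted p under 0.05. DESeq2 called 379 (238 higher, 141 lower). The edgeR count was 43 without olig2 library 1, 65 without olig2 library 2, 0 without nkx2.2a library 1, 3 without nkx2.2a library 2 or dbx1b library 2, and 4 without dbx1b library 1. The ribosomal list changed direction without nkx2.2a library 1 (adjusted p = 0.702) or dbx1b library 1 (0.486) and missed the threshold without olig2 library 2 (0.0515). It was also lost with the replicate block (0.0874), RLE scaling (0.0724) or omission of LOC101882117 (0.0516). The pMN call was lost whichever library was left out (adjusted p from 0.0610 to 0.158) and under RLE scaling (0.0517), and the hatching gland call without any library but dbx1b library 2 (up to 0.264). Also lost were the p0 to p2 call without dbx1b library 1 (0.0662), the cell cycle call without nkx2.2a library 1 (0.0940), and the stress call without nkx2.2a library 1 (0.0585) or dbx1b library 1 (0.0680). Of the 27 list examples named, chosen after their values and cut after their stability were seen, 14 kept their call under all 10 alternatives, and nkx2.2a library 2 cost the most calls, 9.

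The comparison of olig2 with dbx1b cells sets the pMN against the p0 sort. At camera's preset correlation, the olig2 cells carried more pMN transcripts and fewer transcripts of presomitic mesoderm, tailbud and stress genes. None of these 3 lists passed with an estimated correlation (camera adjusted p = 0.187 to 0.348), but all 3 passed with fry (fry adjusted p = 0.0136 to 0.0495). Lists that passed with fry but not with camera were retinoic acid, FGF and Wnt genes (fry adjusted p = 0.0136), axon guidance genes (0.0460) and dorsal neural tube genes (0.0495). The estimated correlations of the tailbud (-0.00777) and pMN (-0.0561) lists lay below the preset 0.01. Correlated members therefore do not account for the loss of these calls. The estimate for the stress list was 0.0274. The pMN list had a median of 1.85, with 4 of 12 higher and 0 lower adjusted over the list alone by edgeR (camera adjusted p = 0.00848; adjusted p = 0.348 with an estimated correlation). Its member nkx6.1 stood at 238 ± 79.7 against 23.5 ± 5.18 CPM (10.1-fold), and olig2 itself was higher by 5.86 ± 0.87 on the log2 scale, from 5.37 without dbx1b library 1 to 6.58 without dbx1b library 2. Of 24 presomitic mesoderm and tailbud members, 14 were lower and 0 higher (median -2.84, camera adjusted p = 5.3e-08; adjusted p = 0.187 with an estimated correlation). Among T-box genes, tbx6 was lower by a log2 fold change of -2.86 ± 0.71, and tbx16 was at 3.31 ± 4.35 against 157 ± 9.73 CPM (-5.58 ± 1.38, and -9.31 without olig2 library 1). The gene msgn1 was at 11.4 ± 0.252 against 212 ± 83.9 CPM, and the clock genes her1 and her7 were at 2.69 ± 1.79 against 84.7 ± 42.8 CPM and 7.01 ± 2.16 against 87.4 ± 21.9 CPM. Stress and dissociation genes had a median of -1.12, with 6 of 45 lower and 1 higher (camera adjusted p = 7.8e-04; adjusted p = 0.348 with an estimated correlation). The lower members included phlda3 (0.508 ± 0.288 against 64.5 ± 0.497 CPM), the ubiquitin ligase gene mdm2 (59.8 ± 1.08 against 237 ± 22.1 CPM), ccng1 (715 ± 29.5 against 1695 ± 197 CPM) and the cell cycle inhibitor gene cdkn1a (2.52 ± 0.122 against 32.3 ± 1.36 CPM).

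**Figure D2:**
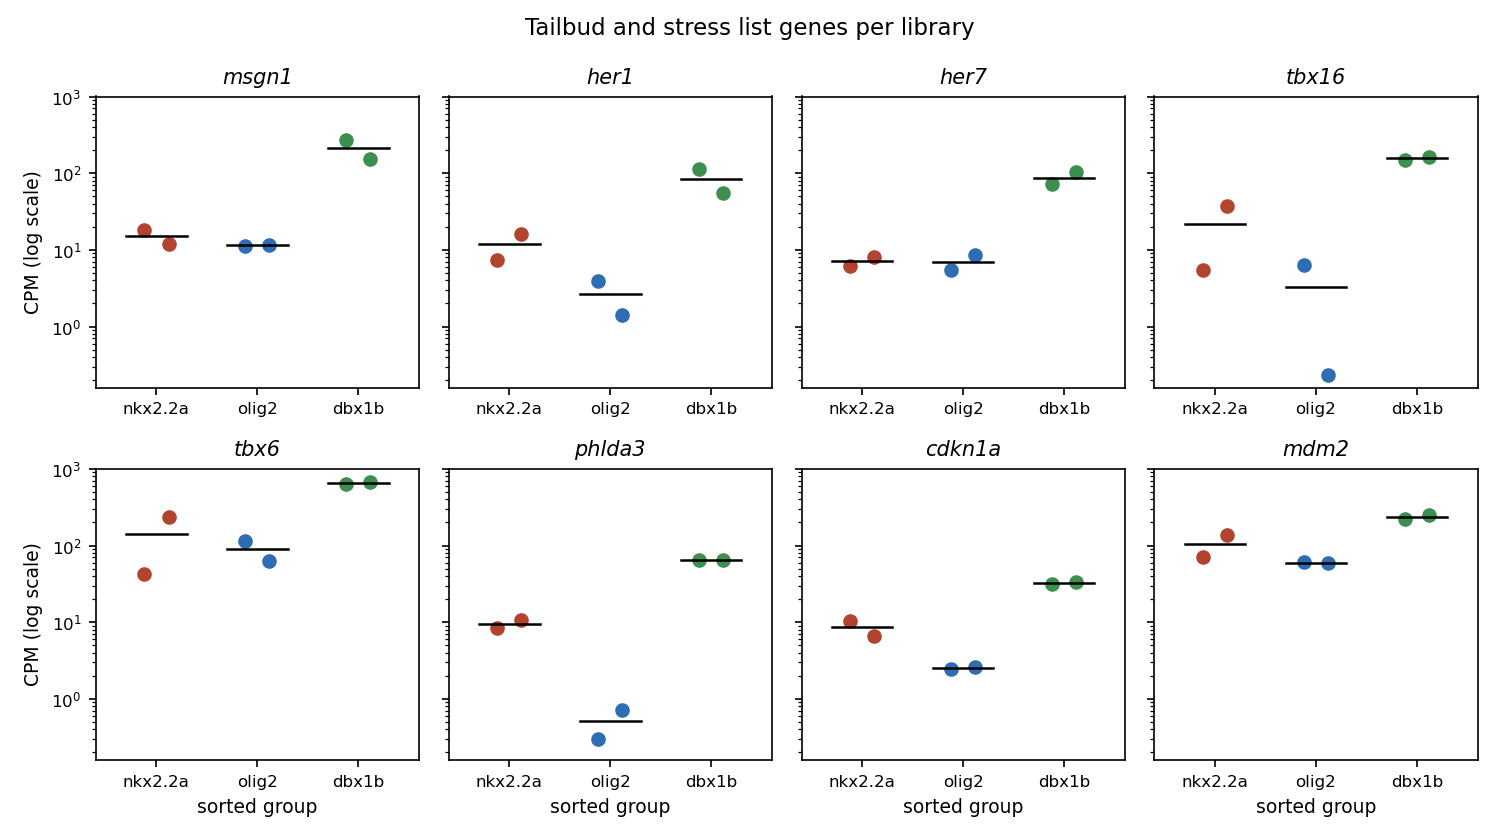
CPM (log scale) of 5 presomitic mesoderm and tailbud genes and 3 genes of the stress list in each library, by sorted group. Points are libraries, library 1 on the left, and bars are means of 2 libraries. In every panel both dbx1b libraries lie above the other 4, for tbx6 at 653 ± 27.1 CPM on average and for phlda3 at 64.5 ± 0.497 CPM.

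Further lists held members that passed over the list alone without passing camera as a whole. Ventral midline genes went both ways, with 4 of 21 higher and 3 lower (camera adjusted p = 0.373): nkx2.9 (5.98 ± 1.13, and 9.05 without dbx1b library 2) and ntn1b (2.37 ± 0.55) were higher and sulf1 lower (-1.97 ± 0.36) in olig2 cells. Neuronal differentiation genes had 4 of 27 higher and 0 lower (median 0.80, camera adjusted p = 0.0694), including the pan-neuronal gene elavl3, at 1302 ± 107 against 407 ± 68.9 CPM, and the transcription factor genes myt1a (1.90 ± 0.44) and insm1b (2.01 ± 0.52). The retinoic acid, FGF and Wnt list had 6 of 55 lower and 0 higher (camera adjusted p = 0.0608), including cyp26c1 (-2.67 ± 0.47), cyp26a1 (-2.81 ± 0.74, and -4.59 without olig2 library 2), the FGF ligand gene fgf8a (-2.82 ± 0.69) and the FGF pathway gene il17rd (-2.40 ± 0.54). Axon guidance genes had 3 of 35 lower and 1 higher (camera adjusted p = 0.199), with nrp2b (-1.74 ± 0.40) and the Slit receptor gene robo1 (-2.28 ± 0.57) among the lower. Neural crest markers split into 2 higher and 3 lower of 22 (camera adjusted p = 0.686), with tfap2a higher (2.18 ± 0.60) and pax3a lower (-2.53 ± 0.69). Of the 22 p0 to p2 genes, dbx1b alone passed (camera adjusted p = 0.0694), and Hox genes had a median of -0.54 with 0 of 44 past edgeR's test over the list alone (camera adjusted p = 0.0694).

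Over all 19129 genes edgeR called 0, the smallest adjusted p being 0.0617, with 1823 genes at unadjusted p under 0.05. DESeq2 called 696 (307 higher, 389 lower). The edgeR count was 4 without nkx2.2a library 2, 7 without olig2 library 1, 3 without olig2 library 2 or dbx1b library 1, and 6 without dbx1b library 2. The pMN call was lost without olig2 library 2 (adjusted p = 0.249). Of the 27 list examples named, chosen after their values and cut after their stability were seen, 11 kept their call under all 10 alternatives, and dbx1b library 2 cost the most calls, 15. The least stable were cdkn1a, which kept its call in 5 of 10, and ccng1, mdm2 and insm1b, which kept theirs in 6.

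Markers of other trunk tissues were tested in the same way. In nkx2.2a over olig2, nkx2.2a over dbx1b and olig2 over dbx1b cells, camera gave adjusted p = 0.0930, 0.240 and 0.686 for somite and muscle markers and 0.210, 0.291 and 0.790 for blood. It gave 0.191, 0.727 and 0.504 for endothelium, 0.768, 0.727 and 0.504 for endoderm and yolk, and 0.226, 0.524 and 0.686 for pronephros and lateral mesoderm. Dorsal neural tube genes gave 0.225, 0.240 and 0.0608, and Hedgehog pathway genes and targets 0.276, 0.980 and 0.469. The median or mean of a list and camera's direction differed in sign for 3, 5 and 4 lists, 0 of them past the threshold. For cadherins in nkx2.2a over olig2 cells, for example, the median was -0.13 and the mean 0.37.

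**Figure D3:**
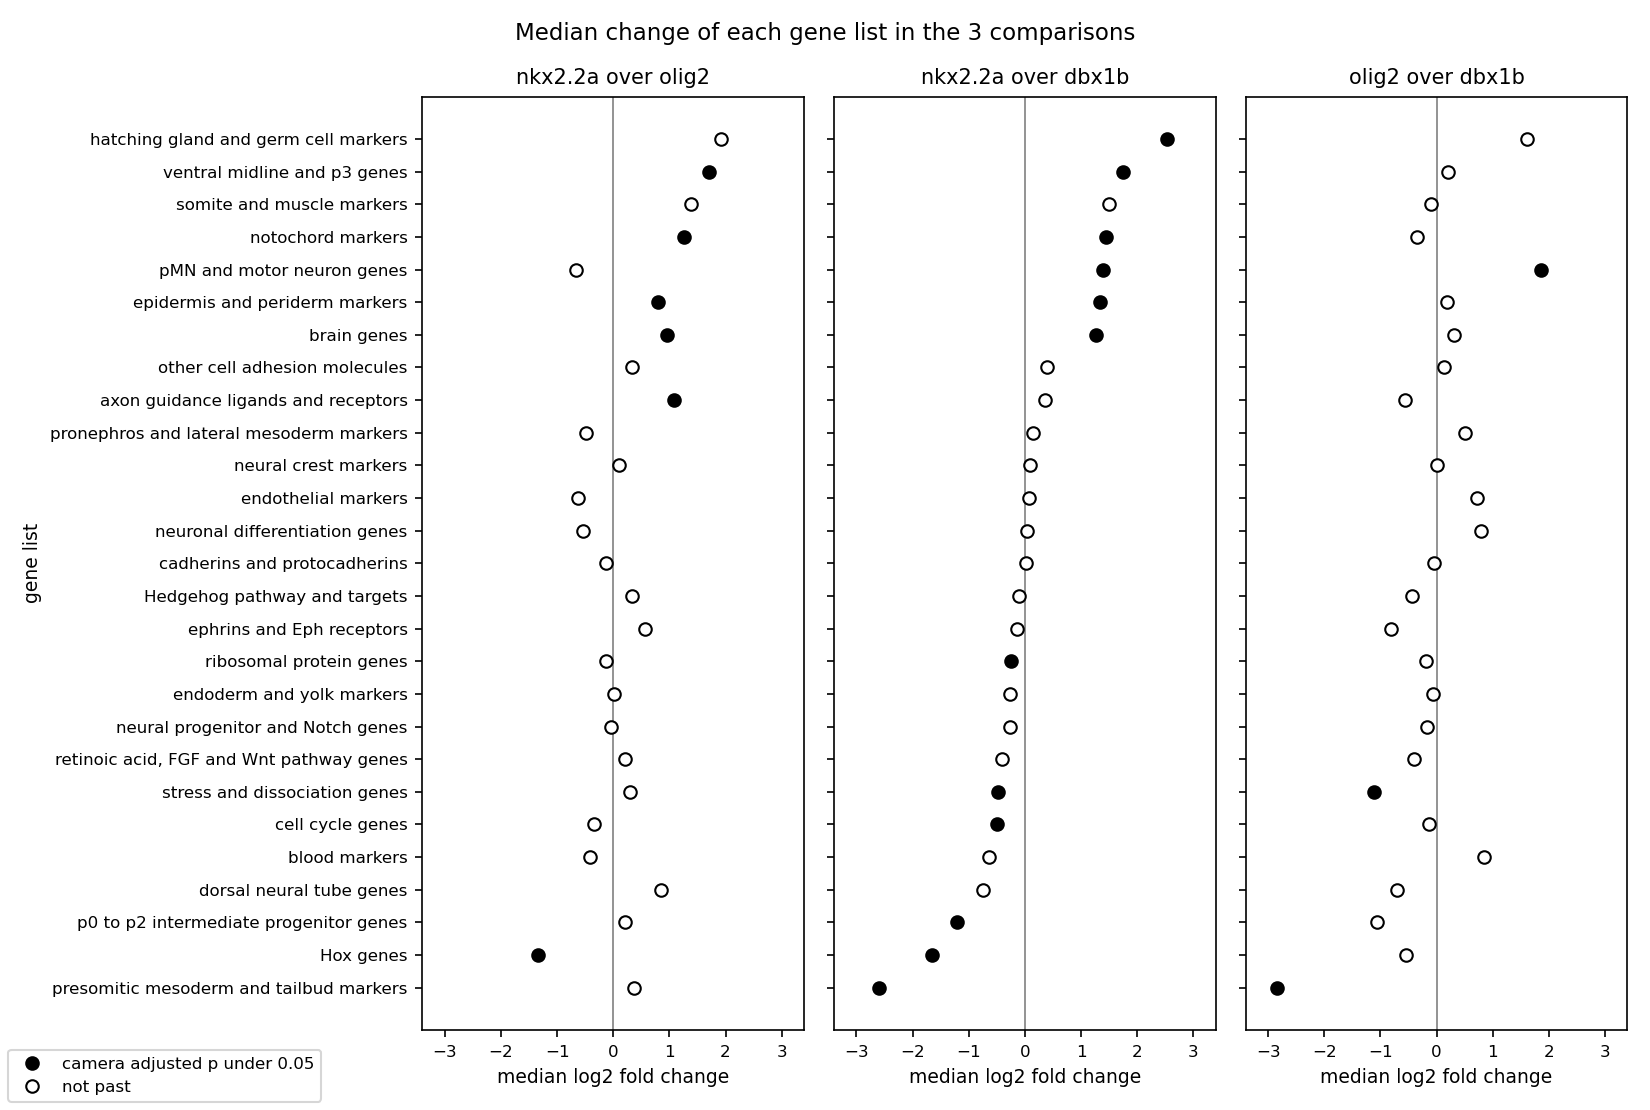
Median log2 fold change of each of the 27 gene lists in the 3 comparisons. Filled points mark lists with camera adjusted p under 0.05 at the preset correlation of 0.01, and open points the others. Of the 27 lists, 6, 12 and 3 passed, with the tailbud list lowest in nkx2.2a over dbx1b (-2.60) and olig2 over dbx1b cells (-2.84).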

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

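Fragments in place of reads, the bias-adjusted dispersion, the 10 CPM filter, summed FPKM, voom and the omission of LOC101882117 were chosen after seeing the data. Counts of called genes depended on the tool and filter. For nkx2.2a over olig2, nkx2.2a over dbx1b and olig2 over dbx1b, edgeR called 0, 1 and 0 genes. DESeq2 called 569, 379 and 696, and edgeR without a filter 233, 238 and 292. The bias-adjusted dispersion gave 1, 31 and 3, and with a 10 CPM filter 29, 133 and 91. Voom with quality weights gave 0, 2 and 2, fragments 0, 1 and 2, a 10 CPM filter alone 0, 1 and 2, and the 4 compared libraries 0, 2 and 0. Library totals alone and transcripts as features both gave 0, 0 and 0, RLE scaling 0, 1 and 0, summed FPKM 0, 1 and 0, and omission of LOC101882117 0, 1 and 0. Leaving out a library gave 0 to 6, 0 to 65 and 0 to 7. The 1 CPM filter kept the 19129 genes already tested and the fold threshold of 1 removed no call, so neither tests anything. With a library left out the filter kept more genes, for example 21706 without olig2 library 1 and 21626 without olig2 library 2. The cause of these changes was not tested. limma-trend on FPKM was planned for values per gene; the FPKM being per transcript, it was run only on sums.

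Replicate numbers did not pair the libraries: the correlations of deviations from the group means were 0.0235, -0.0142 and 0.0153. With the number as a block, edgeR called 0, 1 and 3 genes, and 8, 11 and 6 lists passed in place of 6, 12 and 3.

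camera's 6, 12 and 3 lists became 0, 0 and 0 with an estimated correlation and 0, 1 and 6 with fry, and 4 to 11, 7 to 14 and 2 to 9 with a library left out. The ribosomal list in nkx2.2a over dbx1b changed direction without nkx2.2a library 1 (adjusted p = 0.702) or dbx1b library 1 (0.486), its range being 1.0e-06 to 0.702; the cause was not tested. Of 90 reporter values under alternatives, 86 kept direction and call. The exceptions in call lie in nkx2.2a over olig2: olig2 ranged from -3.15 to -1.29 with a library left out and dbx1b from -0.17 without nkx2.2a library 2 to 1.91 without nkx2.2a library 1 (adjusted p = 0.0123). Elsewhere the size depended on the library left out: dbx1b ranged from -4.12 to -2.01 in nkx2.2a over dbx1b and from -4.44 to -3.57 in olig2 over dbx1b. For nkx2.2a the ranges were 4.01 to 5.72, 8.37 to 9.61 and 3.11 to 4.99 in the 3 comparisons, and for olig2 2.69 to 4.64 in nkx2.2a over dbx1b and 5.37 to 6.58 in olig2 over dbx1b. Of 90 adhesion values, 76 kept both and 2 changed sign: pcdh19 in nkx2.2a over dbx1b, from -0.35 without nkx2.2a library 1 to 0.70 without nkx2.2a library 2, and cdh11 in nkx2.2a over olig2, from 0.33 without olig2 library 1 to -1.23 without olig2 library 2. Left-out libraries leave 1 sample in a group, assumed to vary like the others. Depth limits genes near 1 CPM, such as nkx2.2a in dbx1b cells (3 and 9 fragments).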

Other observations

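The bias-adjusted dispersion, an alternative chosen after seeing the data, called genes outside the lists. In nkx2.2a over dbx1b cells it called 31 genes (23 higher, 8 lower), each with edgeR adjusted p of 0.0469 or less. The sclerotome and pharyngeal pouch gene pax1a stood at 150 ± 89.8 CPM in nkx2.2a cells, 0.237 ± 0.335 CPM in olig2 cells and 0.270 ± 0.382 CPM in dbx1b cells. The epidermal transcription factor gene grhl3 stood at 124 ± 14.2, 5.23 ± 2.66 and 5.84 ± 2.91 CPM, and the sulfatase gene sulf2b at 204 ± 113, 146 ± 42.0 and 15.22 ± 3.18 CPM in the same order. Several hatching gland protease genes were called together with relatives such as zgc:174153 (595 ± 97.6 against 2.88 ± 3.31 CPM) and zgc:174855 (510.3 ± 131 against 5.03 ± 5.84 CPM), which carry a cathepsin L synonym; reads can be shared between such copies, so they are uncertain as separate genes.

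Higher in dbx1b cells were nav2b, a neuron navigator gene, at 1612 ± 628 CPM against 262 in nkx2.2a and 162 ± 20.9 in olig2 cells, and stm, the starmaker gene of otolith mineralisation, at 1254 ± 238 against 285 ± 55.2 and 127 ± 26.6 CPM. These 2 were also lower in olig2 over dbx1b cells, by -3.31 ± 0.38 and -3.31 ± 0.36 on the log2 scale (edgeR adjusted p = 0.0117), where the third call was the uncharacterised si:ch211-116m6.3, at 730 ± 37.2 against 49.2 ± 16.1 CPM. The exocyst-related gene exoc3l1 stood at 209.8 ± 111 CPM in dbx1b cells, 2.13 ± 2.58 in nkx2.2a and 2.997 ± 3.81 in olig2 cells.

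In the explanations weighed next, the tests of posterior tissue and of epidermal cells were chosen after the result was seen, and the patterns were found in the same data. A transgenic line, GFP form or sort effect is open for each of them and was not tested.

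Presomitic mesoderm and tailbud genes were higher in dbx1b libraries. Their median log2 difference from the mean of the other groups was 2.76 over 24 genes. The list did not pass with an estimated correlation (camera adjusted p = 0.139 against nkx2.2a and 0.187 against olig2 cells). It passed with fry (fry adjusted p = 0.0231 and 0.0136). With all libraries thinned to 3.25 M fragments the median was 2.73 (bootstrap SE 0.55). CPM are scaled for depth already, so thinning moves mainly genes with few fragments. Members such as tbx6, at 653 CPM in dbx1b cells, are far from that. At equal depth the median of the 24 genes thus stayed at 2.73, which argues against the number of fragments as its source. Library features that go with depth, such as the mapped share, were not tested. Presomitic mesoderm cells in the sort are a candidate explanation. For 19 further genes expressed in that tissue the median was 0.76 (SE 0.28), with 14 above 0, at percentile 99.96 of matched random lists. The most abundant of them in dbx1b cells were fn1b (736 ± 157 CPM) and epha4a (517 ± 8.403 CPM). Since 15 of the 19 are also in another list, the set is not particular to presomitic mesoderm. The random lists were matched on mean expression only, and the SE comes from draws over genes. Neither allows for genes that vary together. This test therefore cannot tell presomitic cells from other sources of these transcripts. More posterior tissue is another candidate, since Hox paralog groups 9 to 13 differed by 1.94 and groups 1 to 4 by 0.91, 1.03 apart (SE 0.24). Over all Hox genes the median was -0.54 in olig2 over dbx1b cells but -1.34 in nkx2.2a over olig2 cells. The test uses the mean of both other groups. It therefore cannot tell more posterior tissue in the dbx1b samples from more anterior tissue in the nkx2.2a samples. Presomitic cells and posterior tissue stay open together. The tail was removed before sorting, per the labels, and the sort on GFP would remove cells that carry none. How far either step took such cells away was not tested.

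The 72 epidermis, hatching gland and brain genes, most of which passed no test singly, had a median log2 difference of 1.48 towards the nkx2.2a libraries. After thinning it was 1.39 (SE 0.26), and library features that go with depth were again not tested. The hatching gland list did not pass against olig2 cells (camera adjusted p = 0.0639). The brain and epidermis calls against olig2 cells and the hatching gland call against dbx1b cells are lost without single libraries. None of the 3 lists passed with an estimated correlation (camera adjusted p = 0.239 to 0.565). Epidermal cells, which the sort on GFP would remove if they carry none, cannot be told apart from expression by the sorted cells. The 10 most abundant epidermal members differed by a median of 1.09 (SE 0.45). The 9 members past the list test, 5 of which are among the 10, differed by 1.96. Those 9 were picked by their differences in the same data, which raises their median. The gap between 1.09 and 1.96 therefore decides nothing. In nkx2.2a, olig2 and dbx1b cells, krt4 stood at 499.5 ± 70.9, 566 ± 152 and 318 ± 127 CPM and cyt1 at 259 ± 46.1, 271 ± 64.9 and 179 ± 83.7 CPM, while krt18 stood at 486 ± 136, 109 ± 21.8 and 147 ± 71.0 CPM. Head tissue that escaped dissection could contribute to the brain genes, but 18 further head genes in no list had a median of 0.39 (SE 0.46), at percentile 77.45 of random lists, which decides nothing.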
